A study of Mus musculus with 32 samples.

How the data were processed

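The series holds poly(A)-selected, strand-specific RNA sequencing of mouse CD4+ T cells, the helper and regulatory T cell lineage, from 32 libraries. Per the labels' protocols, the cells came from spleen and from inguinal and axillary lymph nodes of C57BL/6J mice, and libraries were made with the NEBNext Ultra II directional kit. The labels give a genotype, wild type (WT) or knockout (KO) of Nr4a1, the gene for the nuclear receptor Nur77, and a treatment. Cells were unstimulated, stimulated for 12 h with antibodies to CD3 and CD28, or stimulated in the presence of XCT790 or of a compound coded CompA, each at 10 µg/ml. This makes 8 groups of 4 libraries. The protocol text describes stimulation without excepting the samples labelled control, and the groups here follow each sample's own labels, in which control stands for unstimulated. The vehicle given to stimulated cells without an inhibitor is not given in the sources used here. Nothing in the labels says that the 4 libraries of a group came from separate animals, so every p-value measures the spread between these samples, which may be technical.

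Each sample has 1 deposited file of read counts per gene, whole numbers that the authors did not normalize. The submitters' processing notes name Trimmomatic 0.36 (a read trimmer), HISAT2 2.1.0 (an aligner), SAMtools, HTSeq 0.9.1 (a read counter), R 3.4.4 and DESeq2 1.18.1 and the mm10 genome build. The notes used here give neither settings nor an annotation version, and whether HTSeq counted by strand is not stated. Overlapping and antisense genes and near-identical copies, such as Hspa1a and Hspa1b, may therefore share reads. Each file lists 24302 genes and 5 summary lines that name no gene. Reads outside annotated genes were 5.31 to 13.3 percent of the listed reads, and ambiguous reads 1.1 to 2.32 percent. For every 100 counts in genes there were 58.6 to 91.3 reads listed as not uniquely aligned. These lines stayed out of library sizes and tests. Gene coordinates are those of GRCm38 (mm10) and are 1-based. They were looked up by symbol or synonym for 24153 of the 24302 names.

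Counts were tested with the quasi-likelihood F test of edgeR 4.0.16 (limma 3.58.1, R 4.3.3), with TMM factors and edgeR's default filter on low counts, which left 12332 genes. All 32 libraries entered 1 fit with a mean per group, and 15 contrasts were drawn from it. Adjusted p-values are Benjamini-Hochberg values over the 12332 genes, and a gene was called at an adjusted p under 0.05. Log2 fold changes carry the standard error (SE) of the fit. Levels are CPM (counts over the library total, in the unit of that name) scaled by TMM, as mean ± SD of 4 libraries. Where a group had no count for a gene, the fold is a lower bound against 3 counts over the group, and it covers counting error only. The fitted log2 changes of such genes, and of genes with 1 to 3 counts in a group, depend on the prior count.

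Of 32 gene lists fixed beforehand, covering T cell function, metabolism, stress responses, proliferation and markers of other cell types, 31 had at least 5 tested members. They were tested with camera at a preset correlation between genes of 0.01, two-sided, and adjusted over the lists of a contrast. Each list was also tested with the correlation estimated from the data, and member counts are given over all genes and adjusted over the list alone. The genes named are part of those a rule fixed before the files were opened takes. It takes Nr4a1, Nr4a2, Nr4a3 and Esrra. It takes the 8 largest rises and the 8 largest falls of 4 comparisons (stimulation in WT, KO against WT when stimulated, and each inhibitor in WT) and the 3 largest of each direction elsewhere. These came from called genes with a mean of at least 10 CPM in the higher group and no overlap between libraries, a condition dropped for interactions. It also takes up to 4 members with the smallest adjusted p of each list described. The groups, comparisons, lists, naming rule and most alternatives were set before the data were examined. Subtraction of an estimated unstimulated share from the WT stimulated libraries, and omission of KO replicate 2, were added after seeing the data.

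The library numbers in the titles run from 1 to 16 for WT and from 25 to 40 for KO, so library order and genotype cannot be told apart. They fall into 8 runs of 4 numbers, each with 1 library of every treatment. Whether a run shares an animal or a day is not stated. Deviations from the group means were correlated across genes between libraries of the same run. In KO every pair of treatments had same-run correlations between 0.19 and 0.69. In WT they were 0.37 to 0.56 for unstimulated with stimulated cells and 0.17 to 0.49 for XCT790 with CompA, but were not above 0.1 in every run for the other pairs. The run was therefore fitted as a replicate block in an alternative, as a fixed term in edgeR within genotype and as a random term in limma-voom between genotypes. No pair of replicates agreed within sampling noise, with chi-square values of 2.78 to 120 per degree of freedom.

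For the subtraction, 125 genes were used that had at least 20 CPM in unstimulated WT cells and had fallen under 3 percent of that in both WT inhibitor groups and, in KO stimulated cells, to under 5 percent of the KO unstimulated level. The median ratio of their counts in each WT stimulated library to the unstimulated library of the same run was taken as that library's share, and the share of the unstimulated counts was subtracted before refitting. The scripts were tested on simulated data. With 200 genes changed in counts drawn from these libraries, the test of KO against WT stimulated cells recovered 44.6, 83.6 and 89.4 percent of genes changed 1.5-, 2- and 4-fold, and 5.88 percent of its calls were false. Simulated additions of 0.05, 0.2, 0.4 and 0.3 of an unstimulated library were estimated as 0.0641, 0.206, 0.409 and 0.306 from 64 genes.

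The alternatives were DESeq2 size factors, upper-quartile factors or library totals in place of TMM, no filter or a minimum of 1 CPM in 4 libraries, the Wald test of DESeq2 1.42.0, limma-voom, the replicate block, fits of only the groups compared, and each library left out in turn. Comparisons that share libraries were set beside 20 simulations of unchanged groups and beside 6 ways of dividing the shared libraries. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15. Gene counts per library ranged from 16 to 23.7 megacounts, which sets the precision of genes with low counts. The list of mitochondrially encoded transcripts was not analysed here.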

Results

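Gene expression was measured by RNA sequencing in mouse CD4+ T cells of 2 genotypes under 4 conditions, with 4 libraries in each of the 8 groups. Libraries labelled WT or KO for Nr4a1 came from unstimulated cells, from cells stimulated for 12 h through CD3 and CD28, and from cells stimulated with XCT790, an inverse agonist of the estrogen-related receptor ERR-alpha, or with the compound CompA. Gene counts per library averaged 18.1 to 18.9 megacounts in the WT groups and 18.4 to 20.2 in the KO-labelled groups. Between 13060 and 15148 genes had at least 1 count in a library.

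Nr4a1, the gene targeted in the KO (chromosome 15, 101253902 to 101274795), encodes Nur77, a nuclear receptor that T cell receptor signals induce. Its transcript was not lower in any KO-labelled group. It stood at 71.6 ± 21.4 CPM in WT and 94.2 ± 10.9 CPM in KO-labelled unstimulated cells, and at 166 ± 32.7 and 332 ± 128 CPM after stimulation. With XCT790 the levels were 178 ± 11.8 and 284 ± 74 CPM, and with CompA 355 ± 28.7 and 548 ± 164 CPM (SD, n = 4 each). The KO-labelled level was higher by 1.99-fold in stimulated cells (edgeR adjusted p = 0.0015), a call lost with the estimated unstimulated share subtracted from the WT libraries (log2 difference 0.69, adjusted p = 0.0585). The differences did not pass in unstimulated cells (adjusted p = 0.17), with XCT790 (0.059) or with CompA (0.09). Counts over the whole gene do not show whether the transcript encodes a full protein, and how the targeted allele was made is not given in the sources used here. The groups are therefore called KO-labelled throughout. An exchange of the genotype labels was not tested for and stays open, and it would turn every genotype direction.

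The related receptor genes Nr4a2 (chromosome 2, 57106830 to 57124003) and Nr4a3 (chromosome 4, 48045078 to 48086447) were higher in KO-labelled cells before stimulation. Nr4a2 stood at 4.42 ± 0.723 CPM against 1.02 ± 0.398 CPM in WT (4.23-fold, adjusted p = 4.8e-05), and Nr4a3 at 13.1 ± 0.791 against 6.01 ± 1.42 CPM (2.16-fold, adjusted p = 1e-04). After stimulation both genes reached similar levels in the genotypes, 13.2 ± 3.57 and 12.7 ± 5.2 CPM for Nr4a2 (adjusted p = 0.89) and 66.2 ± 12 and 61 ± 17 CPM for Nr4a3 (adjusted p = 0.64). The induction by stimulation was smaller in KO-labelled cells, with interaction log2 fold changes of -2.02 ± 0.42 for Nr4a2 (SE, adjusted p = 0.001) and -1 ± 0.25 for Nr4a3 (adjusted p = 0.0045). Nr4a1 and Nr4a3 rose with CompA in both genotypes. In WT, Nr4a1 rose 2.13-fold (adjusted p = 0.00046) and Nr4a3 to 141 ± 23.7 CPM (adjusted p = 2.1e-06), and in KO-labelled cells they rose 1.65-fold (adjusted p = 0.024) and 1.88-fold (adjusted p = 0.00041). The KO Nr4a1 call was lost without stimulated replicate 1, 3 or 4 or CompA replicate 1 (adjusted p = 0.0514, 0.0784, 0.0847 and 0.143) and in the fit of only the 2 groups (0.157). Esrra (chromosome 19, 6910977 to 6922048), which encodes ERR-alpha, stood at 37.7 ± 4.93 CPM in WT and 35.3 ± 5.13 CPM in KO-labelled stimulated cells. It fell with XCT790 by 0.53 on the log2 scale in WT (SE 0.13, adjusted p = 0.003) and by 0.61 in KO-labelled cells (SE 0.13, adjusted p = 0.004). With CompA its log2 fold changes were -0.11 and -0.02 (adjusted p = 0.57 and 0.94).

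**Figure D1:**
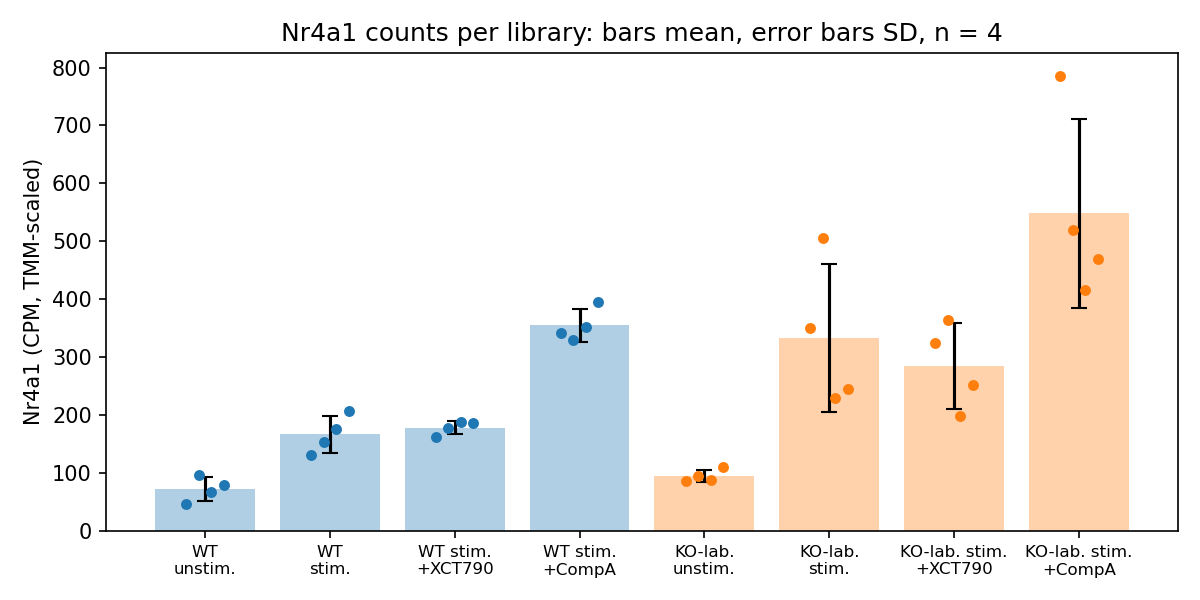
Nr4a1 counts in CPM for each of the 32 libraries (points) with the mean of each group (bars) and its SD (error bars, n = 4). The KO-labelled means were at or above the WT means, 332 against 166 CPM when stimulated.

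Markers of other cell types were present in the unstimulated libraries and stayed in the WT stimulated libraries. Myeloid and dendritic marker genes together stood at 2620 ± 391 CPM in WT and 1400 ± 445 CPM in KO-labelled unstimulated cells (SD, n = 4). After stimulation they stood at 819 ± 287 CPM in WT but at 174 ± 27.1 CPM in KO-labelled cells, at 144 ± 33.8 CPM in WT with XCT790 and at 194 ± 39.7 CPM in WT with CompA. B cell markers showed the same order in WT, with 2210 ± 553 CPM unstimulated, 854 ± 326 CPM stimulated, 310 ± 27.5 CPM with XCT790 and 416 ± 6.84 CPM with CompA. A set of 125 genes that the other stimulated groups had nearly lost remained in the 4 WT stimulated libraries at 0.206, 0.35, 0.29 and 0.197 of the unstimulated level, by library totals. In the other stimulated groups the ratio was between 0.00262 and 0.0167. Every comparison with WT stimulated cells therefore also compares libraries that differ in these genes, and values with the estimated unstimulated share subtracted, an alternative chosen after seeing the data, stand beside their list tests and counts. Among KO-labelled libraries, replicate 2 had the highest B cell marker sum in each condition, 3794 CPM unstimulated and 1319 CPM stimulated, against 1260 to 1838 and 257.2 to 381.7 CPM in the other replicates.

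**Figure D2:**
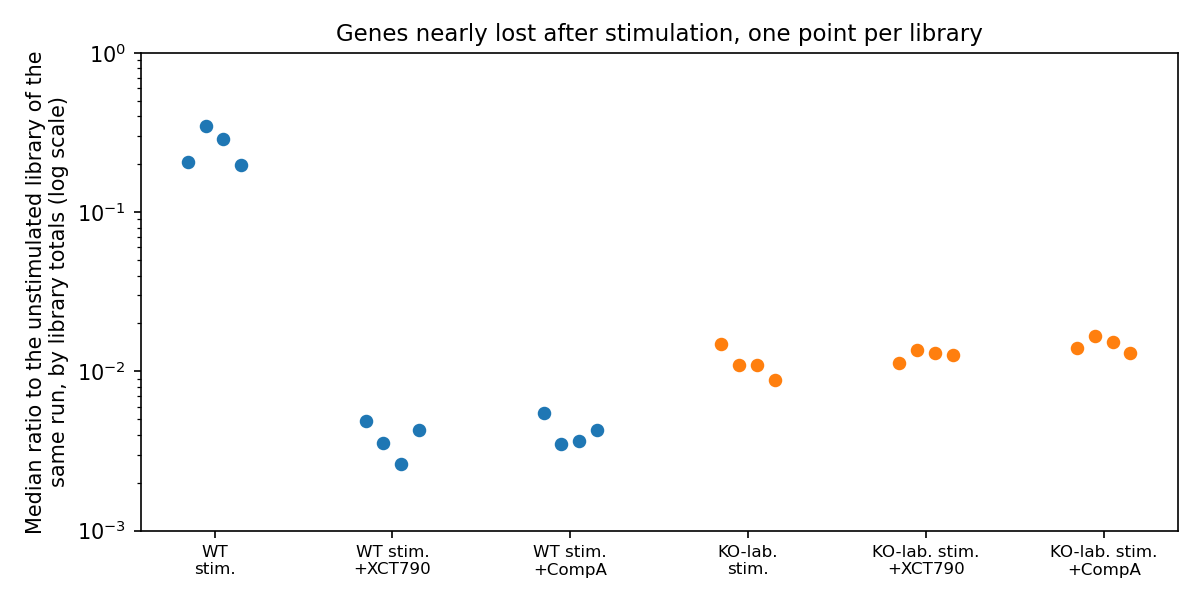
Median ratio to the unstimulated library of the same run of library numbers, by library totals, on a log axis, over 125 genes that stimulated cells had nearly lost, with 1 point for each stimulated library. The WT stimulated libraries lie between 0.197 and 0.35 and the libraries of the other 5 groups between 0.00262 and 0.0167. The WT inhibitor and KO stimulated groups were used to choose the genes.

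The first comparison asks how CD4+ T cells answered to stimulation in KO-labelled libraries. Effector cytokine, ribosome biogenesis, oxidative phosphorylation and replication genes rose, and genes of resting T cells and of macrophages fell. Il3, a growth factor for blood cells, rose from no count to 10.3 ± 3.5 CPM, at least 327-fold higher. Crabp2, which binds retinoic acid, rose from 0.0729 ± 0.0615 to 42.6 ± 23.7 CPM, and Fosl1, a subunit of the AP-1 transcription factor, rose 239-fold. Among effector cytokines 17 of 20 rose and 1 fell (17 and 1 adjusted over the list alone), with a median log2 fold change of 3.65, also with Il3 and Il5 at their bounds (camera adjusted p = 0.013). With an estimated correlation the adjusted p = 0.38. Il2, the main T cell growth factor, rose 109-fold to 100 ± 62.3 CPM, and the chemokine genes Ccl3 and Ccl4 rose 15.1-fold and 34.8-fold.

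Ribosome biogenesis genes rose in KO-labelled cells in all 23 members (also over the list alone), with a median of 2.51 (camera adjusted p = 4.1e-21, and adjusted p = 0.037 with an estimated correlation). Of 75 oxidative phosphorylation genes 73 rose (73 over the list alone), with a median of 1.42 (camera adjusted p = 5.1e-10, and adjusted p = 0.49 with an estimated correlation). Cycs, which encodes cytochrome c, rose 7.02-fold and Atp5b, the ATP synthase beta subunit, rose 3.79-fold to 3320 ± 343 CPM. DNA replication genes rose in 29 of 31 members and fell in 1 (29 and 1 over the list alone), with a median of 1.87 (camera adjusted p = 2.8e-05, and adjusted p = 0.49 with an estimated correlation).

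Of 18 naive and quiescence genes, 14 fell and 2 rose in KO-labelled cells (14 and 2 over the list alone), with a median of -1.89 (camera adjusted p = 0.00062, and adjusted p = 0.38 with an estimated correlation). Interferon-stimulated genes fell in 20 of 23 members and rose in 2 (20 and 2 over the list alone), with a median of -1.79 (camera adjusted p = 0.0015, and adjusted p = 0.42 with an estimated correlation). Myeloid and dendritic markers fell in 17 of 20 members (17 over the list alone), with a median of -4.49 (camera adjusted p = 3.8e-05, and adjusted p = 0.32 with an estimated correlation). C1qa, a complement gene of macrophages, fell from 143 ± 55 to 1.11 ± 0.435 CPM. The collagen gene Col14a1 fell from 14 ± 5.88 CPM to no count, at least 364-fold lower, and Cd163 fell from 14.5 ± 7.37 to 0.0109 ± 0.0218 CPM. In all 10076 of 12332 genes changed, 4851 up and 5225 down. The share of rises was 48.1 percent, and 37.5 percent with library totals, a scaling that moved the median log2 fold change of all genes by -0.33 (-0.26 with upper-quartile factors).

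The same stimulation in WT libraries raised effector cytokine, ribosome biogenesis and oxidative phosphorylation genes, and genes of resting cells fell. Crabp2 rose 929-fold to 78.3 ± 12.6 CPM, Fosl1 rose from 0.0139 ± 0.0278 to 13 ± 5.22 CPM, and Bdh2 rose from 0.0391 ± 0.0276 to 14.8 ± 4.72 CPM. The chemokine genes Ccl22 and Ccl1 rose 183-fold and 73.2-fold, Il2 rose 139-fold, and Bcat1, an enzyme of branched-chain amino acid breakdown, rose 117-fold. Among effector cytokines 17 of 20 rose (17 over the list alone), with a median of 3.66, also with Il3 and Il5 at their bounds (camera adjusted p = 0.001, and adjusted p = 0.33 with an estimated correlation). All 23 ribosome biogenesis genes rose (also over the list alone), with a median of 2.13 (camera adjusted p = 4.7e-26, and adjusted p = 0.027 with an estimated correlation), Polr1b, a subunit of RNA polymerase I, by 5.97-fold. Oxidative phosphorylation genes rose in 58 of 75 members and fell in 1 (58 and 1 over the list alone), with a median of 0.72 (camera adjusted p = 0.00023, and adjusted p = 0.66 with an estimated correlation).

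Naive and quiescence genes fell in 14 of 18 WT members and rose in 2 (14 and 3 over the list alone), with a median of -1.17 (camera adjusted p = 0.0025, and adjusted p = 0.4 with an estimated correlation). Foxo1, a factor of resting T cells, fell from 431 ± 34.7 to 183 ± 33.7 CPM. The myeloid list fell in 17 of 20 members and rose in 1 (17 and 1 over the list alone), with a median of -1.79 (camera adjusted p = 0.0037, and adjusted p = 0.4 with an estimated correlation). With the unstimulated share subtracted, the medians were 4.12 for effector cytokines, 2.51 for ribosome biogenesis, 0.96 for oxidative phosphorylation, -2.14 for the naive and -5.7 for the myeloid list (camera adjusted p at most 0.0041, and adjusted p = 0.33, 0.011, 0.7, 0.22 and 0.26 with an estimated correlation), and 9939 genes changed. The largest falls were 3.89-fold to 4.25-fold, in the macrophage receptor genes Marco and Sirpb1a, in Cmbl, Vstm4, Epb4.1l3, the chemokine gene Ccl6 and Tspan15, and in Dntt, the terminal transferase of developing lymphocytes. The retained unstimulated share limits these folds, and with it subtracted their log2 fold changes were -11.33 to -6.38. The Ccl6 call was lost without unstimulated replicate 1 (adjusted p = 0.0579). In WT 9037 genes changed, 4254 up and 4783 down. The share of rises was 47.1 percent, and 36.4 percent with upper-quartile factors, which moved the median of all genes by -0.22. Of these genes 3946 rose and 4288 fell in both genotypes, where independent lists would share 1670 and 2030, and 29 changed in opposite directions.

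The comparison of genotypes in unstimulated cells asks what differed before stimulation. KO-labelled cells had higher levels of inhibitory receptors, cytokines and regulatory T cell markers, and lower levels of oxidative phosphorylation genes. In the anergy and exhaustion list 9 of 16 members were higher and 1 lower (9 and 1 over the list alone), with a median of 0.53 (camera adjusted p = 3.1e-06, and adjusted p = 0.13 with an estimated correlation). The inhibitory receptor genes Lag3, Tigit and Pdcd1 stood at 141 ± 41.5, 69.2 ± 20.6 and 94.5 ± 31.6 CPM against 28.7 ± 5.83, 18.8 ± 3.91 and 26.1 ± 9.23 CPM in WT. Among effector cytokines 8 of 20 were higher and 1 lower (8 and 1 over the list alone), with a median of 0.78, or 1 without the 2 genes that had no count in both groups (camera adjusted p = 1e-04, and adjusted p = 0.21 with an estimated correlation). Il21, a cytokine of follicular helper cells, was 8.46-fold higher and Il10, an anti-inflammatory cytokine, was 5.93-fold higher. Regulatory T cell markers were higher in 10 of 13 members (10 over the list alone), with a median of 0.85 (camera adjusted p = 9.5e-07, and adjusted p = 0.21 with an estimated correlation). Nrp1 was 3.29-fold higher, Ikzf2, which encodes Helios, 2.78-fold, Itgae 2.42-fold and the inhibitory receptor gene Ctla4 2.03-fold. Mitosis genes were higher in 13 of 22 members (20 over the list alone), with a median of 1.15 (camera adjusted p = 2e-06, and adjusted p = 0.5 with an estimated correlation).

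Oxidative phosphorylation genes were lower in 70 of 75 members in KO-labelled unstimulated cells (73 over the list alone), with a median of -0.56 (camera adjusted p = 1.8e-13, and adjusted p = 0.55 with an estimated correlation). ERR-alpha targets were lower in 11 of 17 members (11 over the list alone), with a median of -0.33 (camera adjusted p = 0.0046, and adjusted p = 0.5 with an estimated correlation). The largest single differences were in BC018473 (36.2 ± 27.7 against 0.0425 ± 0.0288 CPM), Sostdc1 (12-fold higher) and Cacna1d (9.15-fold higher), and in Adamdec1 (0.0212 ± 0.0245 against 61.1 ± 24.6 CPM), Acvrl1 (8.89-fold lower) and Cd209b (7.25-fold lower). BC018473 was not called with the replicate block (adjusted p = 0.0784) or in limma-voom (0.129). The groups also differed in the myeloid marker sum, 1400 ± 445 against 2620 ± 391 CPM. In all 4454 genes differed, 1543 higher and 2911 lower, and 2060 differed without WT unstimulated replicate 1. The share of higher genes was 34.6 percent, and 71.7 percent with library totals, which moved the median of all genes by 0.21. The fit of only these 2 groups gave 2294 genes.

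After stimulation, effector cytokine genes as deposited were higher in KO-labelled than in WT libraries, and macrophage and resting T cell genes were lower, list differences that did not hold with the unstimulated share subtracted. Il10 stood at 14.1 ± 5.04 against 1.74 ± 0.515 CPM (log2 fold change 3.01, SE 0.36, adjusted p = 1.4e-07). Scg2 was 6.84-fold higher, Il1r2, a decoy receptor for interleukin-1, 5.4-fold, Emp1 5.3-fold, Ttc39c 4.12-fold, Nrn1 4.09-fold, Il21 4.07-fold and Tnfrsf8 3.77-fold. These 8 genes were also called, in the same direction, with the unstimulated share subtracted. Effector cytokines were higher in 9 of 20 members and lower in 1 (10 and 1 over the list alone), with a median of 0.79 (camera adjusted p = 0.00035, and adjusted p = 0.24 with an estimated correlation). With the share subtracted 3 were higher and 1 lower, with a median of 0.39 (camera adjusted p = 0.095, and adjusted p = 0.9 with an estimated correlation). Ifng, the interferon of helper T cells, stood at 149 ± 71.5 against 49.5 ± 17.3 CPM. Regulatory T cell markers were higher in 6 of 13 members and lower in 1 (7 and 1 over the list alone), with a median of 0.63 (camera adjusted p = 0.0025, and adjusted p = 0.63 with an estimated correlation). The median was 0.85 with the share subtracted, and 8 members were higher (camera adjusted p = 3.6e-11, and adjusted p = 0.062 with an estimated correlation). Ctla4 was 2.14-fold higher, Tnfrsf18 1.69-fold and Il2ra, the interleukin-2 receptor alpha chain, 1.53-fold, while Itgae was 2.24-fold lower. Il2ra was not called in the fit of only these 2 groups (adjusted p = 0.05), and Tnfrsf18 and Il2ra were not called with the share subtracted (0.0538 and 0.521), where Itgae turned to a log2 difference of 0.62 (adjusted p = 0.326).

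Myeloid markers were lower in 15 of 20 members in KO-labelled stimulated cells (16 over the list alone), with a median of -3.39 (camera adjusted p = 3.1e-18, and adjusted p = 0.013 with an estimated correlation). C1qa stood at 1.11 ± 0.435 against 102 ± 37.1 CPM. The largest falls were Adamdec1 (from 19.5 ± 14.8 CPM to no count, at least 504-fold lower), Cd163 (0.0109 ± 0.0218 against 20.9 ± 19 CPM), Emr4 (0.0662 ± 0.102 against 51.8 ± 27.1 CPM), Slco2b1 (0.0268 ± 0.0537 against 14.1 ± 9.01 CPM), Hfe (0.0384 ± 0.0482 against 14.7 ± 7.27 CPM), Itgad (0.278 ± 0.219 against 71.1 ± 40.2 CPM), Csf1r (226-fold) and C6 (218-fold). Naive and quiescence genes were lower in 13 of 18 members (14 over the list alone), with a median of -0.92 (camera adjusted p = 1.7e-07, and adjusted p = 0.23 with an estimated correlation). Il7r, the interleukin-7 receptor, stood at 13.5 ± 2.56 against 191 ± 119 CPM and S1pr1, which guides T cells out of lymph nodes, at 34.5 ± 7.75 against 180 ± 37.9 CPM. With the unstimulated share subtracted the list medians turned to 0.25 (myeloid, adjusted p = 0.023, and adjusted p = 0.59 with an estimated correlation) and 0.09 (naive, adjusted p = 0.28), and Adamdec1 and Cd163 alone of the 8 falls kept their call. C1qa and Il7r were not called (adjusted p = 0.576 and 0.846), and S1pr1 was higher in KO-labelled cells.

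Interferon-stimulated genes did not differ as a list between stimulated KO-labelled and WT cells, with 2 of 23 members higher and 4 lower (2 and 4 over the list alone) and a median of -0.09 (camera adjusted p = 0.6). Ddx58, the RNA sensor RIG-I, was 3.93-fold lower. Subtracting the share left 14 members higher, Ddx58 among them, and none lower, with a median of 1.47 (camera adjusted p = 3.3e-15, and adjusted p = 0.062 with an estimated correlation). ERR-alpha targets were higher in 3 of 17 members (1 over the list alone), with a median of 0.12 (camera adjusted p = 0.12). Among them were Idh3a (259 ± 21.6 against 206 ± 17.9 CPM) and Cycs (1.26-fold). Oxidative phosphorylation genes passed in 2 of 75 members (0 over the list alone), with a median of 0.22 (camera adjusted p = 1e-04, and adjusted p = 0.68 with an estimated correlation). The passing members were Cycs and Ndufa10 (1.14-fold). The calls of Idh3a, Cycs and Ndufa10 were lost in the fit of only these 2 groups (adjusted p = 0.067, 0.0995 and 0.288). Those of Cycs and Ndufa10 were also lost without WT stimulated replicate 2, 3 or 4 or KO replicate 1 or 4 (0.0576 to 0.13), that of Ndufa10 without KO replicate 3 (0.0763) and that of Idh3a without WT replicate 2 (0.0737). With the share subtracted the ERR-alpha list turned to a median of -0.08 (camera downward, adjusted p = 0.042, and adjusted p = 0.9 with an estimated correlation) and the oxidative phosphorylation list to -0.03 (adjusted p = 0.27), and none of the 3 genes was called. In all 3111 genes differed, 902 higher and 2209 lower. The share of higher genes was 29 percent, and 41.3 percent with DESeq2 size factors. The fit of only these 2 groups gave 1438 genes, and with the share subtracted 1116 differed, of which 233 higher and 131 lower genes were shared and 248 were called in the opposite direction.

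The genotype comparison within the XCT790 groups does not use the WT stimulated libraries, and the myeloid sums were 193 ± 40.4 CPM in KO-labelled and 144 ± 33.8 CPM in WT cells. The CD8 T and NK sums were 63.5 ± 11.5 and 41.6 ± 2.5 CPM, and the B cell sums 521 ± 361 and 310 ± 27.5 CPM. Regulators of helper lineages, regulatory T cell markers and interferon-stimulated genes were higher in KO-labelled cells. Regulatory T cell markers were higher in 8 of 13 members (11 over the list alone), with a median of 1.07 (camera adjusted p = 2.5e-12, and adjusted p = 0.11 with an estimated correlation). Nrp1 was 4.18-fold higher, Nt5e, the ectonucleotidase CD73, 5.3-fold and Ctla4 2.1-fold. Helper lineage regulators were higher in 6 of 18 members (8 over the list alone), with a median of 0.66 (camera adjusted p = 5.8e-08, and adjusted p = 0.11 with an estimated correlation). Cxcr3, a chemokine receptor of type 1 helper cells, stood at 25.8 ± 4.56 against 5.86 ± 0.431 CPM, and Maf and Prdm1 were 5.75-fold and 5.21-fold higher. Interferon-stimulated genes were higher in 12 of 23 members (13 over the list alone), with a median of 1.34 (camera adjusted p = 3.8e-09, and adjusted p = 0.3 with an estimated correlation).

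The largest differences with XCT790 were Spock2 (12.9-fold higher), Igj, which encodes the immunoglobulin joining chain (34.7 ± 45.4 against 3.31 ± 1.78 CPM), and Emp1 (6.13-fold higher), and Wdfy1 (2.12 ± 0.309 against 27.3 ± 2.07 CPM), Rgcc (5.12-fold lower) and Eno3 (2.89-fold lower). The Igj call was lost with the replicate block (adjusted p = 0.0512), in limma-voom (0.155) and without KO-labelled XCT790 replicate 2 (0.197) or WT XCT790 replicate 1 (0.0721) or 3 (0.0727), and KO replicate 2 carried the highest B cell markers. In all 1173 genes differed, 913 higher and 260 lower. The count fell to 735, 660 and 750 without WT XCT790 replicate 1 or 3 or KO-labelled XCT790 replicate 3.

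With CompA, regulatory T cell, helper lineage and interferon-stimulated genes were higher in KO-labelled cells, and ATF4 stress response genes were lower. The myeloid sums were 231 ± 51.2 CPM in KO-labelled and 194 ± 39.7 CPM in WT cells, the CD8 T and NK sums 82.5 ± 9.39 and 55.1 ± 1.47 CPM, and the B cell sums 644 ± 476 and 416 ± 6.84 CPM. Regulatory T cell markers were higher in 7 of 13 members (12 over the list alone), with a median of 0.94 (camera adjusted p = 6.4e-16, and adjusted p = 0.039 with an estimated correlation). Foxp3, the lineage factor of regulatory T cells, stood at 69 ± 22.6 against 23.7 ± 4.26 CPM, and Nrp1 and Nt5e were 5.33-fold and 7.34-fold higher. Helper lineage regulators were higher in 8 of 18 members (9 over the list alone), with a median of 0.81 (camera adjusted p = 1.3e-08, and adjusted p = 0.081 with an estimated correlation), among them Cxcr3 (3.6-fold) and Maf (5.56-fold). Interferon-stimulated genes were higher in 12 of 23 members (15 over the list alone), with a median of 1.11, or 1.09 with Mx1 at its bound (camera adjusted p = 3.1e-11, and adjusted p = 0.16 with an estimated correlation). Genes of the integrated stress response driven by ATF4 were lower in 9 of 22 members in KO-labelled cells (10 over the list alone), with a median of -0.35 (camera adjusted p = 1.2e-05, and adjusted p = 0.26 with an estimated correlation). Psat1, an enzyme of serine synthesis, stood at 457 ± 67.1 against 715 ± 88 CPM. The largest differences were Spock2 (12.3-fold higher), Igj (27.3 ± 36.1 against 2.36 ± 1.11 CPM) and Emp1 (7.41-fold higher), and Wdfy1 (13.8-fold lower), Rgcc (4.57-fold lower) and Crabp2 (3.73-fold lower). Igj was not called with the replicate block (adjusted p = 0.0816), in limma-voom (0.216) or without KO-labelled CompA replicate 2 (0.224) or WT CompA replicate 1 (0.0814) or 3 (0.0803). In all 950 genes differed, 718 higher and 232 lower, a share of higher genes of 75.6 percent that was 87.4 percent with library totals. The count fell to 586, 549 and 591 without WT CompA replicate 1, 3 or 4 and to 626 without KO-labelled CompA replicate 3. With both inhibitors 544 genes were higher and 123 lower, where independent lists would share 53.2 and 4.89, and 1 differed in opposite directions.

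XCT790 is an inverse agonist of ERR-alpha, and its comparison with stimulated cells asks which genes depended on that receptor's activity or otherwise answered to the compound. In KO-labelled cells amino acid stress and lipid synthesis genes rose, and replication, ribosome biogenesis and interferon-stimulated genes fell. ERR-alpha targets fell in 4 of 17 members (6 over the list alone), with a median of -0.29 (camera adjusted p = 4e-05, and adjusted p = 0.22 with an estimated correlation). These were Esrra itself (from 35.3 ± 5.13 to 23.2 ± 4.51 CPM), Idh3a (from 259 ± 21.6 to 194 ± 18 CPM), Cycs (from 91.3 ± 12.5 to 65.8 ± 9.87 CPM) and Atp5b (from 3320 ± 343 to 2550 ± 350 CPM). The Cycs call was lost without XCT790 replicate 3 (adjusted p = 0.0583), and the Atp5b call without XCT790 replicate 3 (0.14) or stimulated replicate 1 (0.0578). ATF4 stress response genes rose in 7 of 22 members (9 over the list alone), with a median of 0.29 (camera adjusted p = 9.1e-06, and adjusted p = 0.19 with an estimated correlation). Chac1, which degrades glutathione, rose 6.28-fold, Cth, an enzyme of cysteine synthesis, 4.54-fold and Trib3, a pseudokinase, 3.82-fold. Fatty acid synthesis genes rose in 5 of 13 members (6 over the list alone), with a median of 0.51 (camera adjusted p = 9.1e-06, and adjusted p = 0.19 with an estimated correlation). Scd2, a fatty acid desaturase, rose from 59 ± 25.3 to 145 ± 47.7 CPM and Srebf1, a regulator of lipid synthesis, rose 1.58-fold. Lysosome and autophagy genes rose in 7 of 22 members (10 over the list alone), with a median of 0.31 (camera adjusted p = 0.00017, and adjusted p = 0.27 with an estimated correlation).

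DNA replication genes fell in 17 of 31 members with XCT790 in KO-labelled cells (26 over the list alone), with a median of -0.57 (camera adjusted p = 9.7e-14, and adjusted p = 0.26 with an estimated correlation). Ribosome biogenesis genes fell in 9 of 23 members (15 over the list alone), with a median of -0.31 (camera adjusted p = 8e-09, and adjusted p = 0.19 with an estimated correlation). Interferon-stimulated genes fell in 10 of 23 members (13 over the list alone), with a median of -1.04 (camera adjusted p = 7.9e-08, and adjusted p = 0.22 with an estimated correlation). Irf7 fell from 13.9 ± 5.69 to 4.83 ± 0.682 CPM. The largest rises were Gpt2, an alanine aminotransferase (4.28-fold), Slc6a9, a glycine transporter (3.95-fold), and Trib3, and the largest falls were the cytokine genes Il3 (4.84-fold) and Lif (2.85-fold) and Irf7. In all 1390 genes changed, 765 up and 625 down. The share of rises was 55 percent, and 41.5 percent with DESeq2 size factors. In the fit of only these 2 groups 240 genes changed, and Esrra, Cycs, Atp5b and Scd2 were not called (adjusted p from 0.0669 for Esrra to 0.105 for Atp5b). The count was 2642 with the replicate block, 887 without stimulated replicate 1 and 771 without XCT790 replicate 3.

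In WT cells XCT790 raised amino acid stress genes and endoplasmic reticulum chaperones, and macrophage and interferon genes were far lower than in WT stimulated libraries. ATF4 stress response genes rose in 13 of 22 members and fell in 2 (14 and 3 over the list alone), with a median of 0.49 (camera adjusted p = 4.3e-05, and adjusted p = 0.21 with an estimated correlation). Chac1 rose 8.45-fold, Cth 6.62-fold, Trib3 3.28-fold and Eif4ebp1 2.24-fold, and Phgdh, an enzyme of serine synthesis, rose from 249 ± 23.1 to 401 ± 6.02 CPM. Endoplasmic reticulum chaperones rose in 13 of 17 members (14 over the list alone), with a median of 0.46 (camera adjusted p = 1.8e-08, and adjusted p = 0.0068 with an estimated correlation). Calr, which encodes calreticulin, rose from 1380 ± 60.1 to 2090 ± 37.6 CPM. Fatty acid synthesis genes rose in 6 of 13 members and fell in 1 (8 and 1 over the list alone), with a median of 0.43 (camera adjusted p = 0.0056, and adjusted p = 0.34 with an estimated correlation). Scd2 rose 2.38-fold and Acsl3 2.04-fold, and Acss2 fell 2.49-fold. With the unstimulated share subtracted, 4, 6 and 6 members of these 3 lists rose, with medians of 0.21, 0.28 and 0.51, and each stayed past the camera test (adjusted p = 0.00012, 2.5e-06 and 8.1e-07, and adjusted p = 0.33, 0.057 and 0.086 with an estimated correlation), but Phgdh was not called and Acss2 rose. The other largest rises were Slc6a9 (5.11-fold), the amino acid transporter gene Slc1a4 (2.9-fold), Myb (2.34-fold), Akr1c18 (2.23-fold, not called with the share subtracted, adjusted p = 0.118) and Cks2 (2.21-fold).

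ERR-alpha targets passed in 1 of 17 WT members with XCT790, Esrra, which fell (1 over the list alone), and the median was 0.06 (camera adjusted p = 0.33). The median was -0.19 with the share subtracted (camera adjusted p = 0.001, and adjusted p = 0.33 with an estimated correlation). Myeloid markers fell in 15 of 20 members (1 up and 17 down over the list alone), with a median of -4.07 (camera adjusted p = 2e-20, and adjusted p = 0.0059 with an estimated correlation). Emr4 fell from 51.8 ± 27.1 to 0.0146 ± 0.0293 CPM, Cd163 from 20.9 ± 19 to 0.0142 ± 0.0284 CPM, Adamdec1 from 19.5 ± 14.8 to 0.0146 ± 0.0293 CPM and Clec4a1 from 10.3 ± 6.6 to 0.0142 ± 0.0284 CPM. Slco2b1, Ptgs1 and Siglece fell from 14.1 ± 9.01, 20.6 ± 10.7 and 13.9 ± 8.24 CPM to under 0.1 CPM, and Mrc1 fell 500-fold. Interferon-stimulated genes fell in 19 of 23 members (19 over the list alone), with a median of -2.6 (camera adjusted p = 1.4e-12, and adjusted p = 0.13 with an estimated correlation), Irf7 from 22.9 ± 5.2 to 1.73 ± 0.792 CPM. With the share subtracted, the myeloid list had a median of -0.16 while camera leaned upward (adjusted p = 0.46), and the interferon list a median of -0.32 (adjusted p = 0.099), with Irf7 not called (-0.32, adjusted p = 0.785). Of the 8 largest falls Cd163, Adamdec1 and Clec4a1 kept their call. In all 3527 genes changed, 1036 up and 2491 down. The share of rises was 29.4 percent, and 16.9 percent with library totals. Subtraction of the share left 1074 changed genes, 669 up and 405 down, of which 185 rises and 168 falls were shared and 197 were called in the opposite direction.

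CompA is known here by its code name alone, and its comparison with stimulated cells asks which genes answered to it. In KO-labelled cells amino acid stress and lysosomal genes rose, and ribosome biogenesis, replication and cholesterol synthesis genes fell. ATF4 stress response genes rose in 6 of 22 members (8 over the list alone), with a median of 0.24 (camera adjusted p = 0.0013, and adjusted p = 0.62 with an estimated correlation). Lysosome and autophagy genes rose in 9 of 22 members (11 over the list alone), with a median of 0.39 (camera adjusted p = 4e-04, and adjusted p = 0.62 with an estimated correlation). Ribosome biogenesis genes fell in 17 of 23 members (21 over the list alone), with a median of -0.41 (camera adjusted p = 1.9e-12, and adjusted p = 0.33 with an estimated correlation), Nop58 from 769 ± 70.4 to 540 ± 26 CPM. DNA replication genes fell in 10 of 31 members (19 over the list alone), with a median of -0.41 (camera adjusted p = 3.3e-07, and adjusted p = 0.62 with an estimated correlation). Cholesterol synthesis genes fell in 8 of 23 members (11 over the list alone), with a median of -0.35 (camera adjusted p = 2.1e-06, and adjusted p = 0.62 with an estimated correlation). Insig1, a sterol-sensing regulator of the pathway (chromosome 5, 28071412 to 28078662), fell from 109 ± 13.3 to 56.8 ± 10.9 CPM and Lss, lanosterol synthase, fell from 69 ± 12 to 40.3 ± 4.2 CPM. The largest changes were rises of Gpt2 (5.96-fold), Trib3 (4.09-fold) and Pck2, the mitochondrial phosphoenolpyruvate carboxykinase (3.68-fold), and falls of Il3 (2.9-fold), Ifitm2 (2.84-fold) and 1110032F04Rik (2.82-fold). The Il3 call was lost when any of 5 single libraries was left out (stimulated replicate 1 or 2, CompA replicate 1, 2 or 3, with adjusted p from 0.0507 to 0.0878). In all 2378 genes changed, 1255 up and 1123 down (1088 and 1386 with DESeq2 size factors), 3635 with the replicate block and 860 in the fit of only these 2 groups.

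In WT cells CompA raised amino acid stress, amino acid transport and glycolysis genes. Of the ATF4 stress response list 14 of 22 members rose and 1 fell (15 and 1 over the list alone), with a median of 0.82 (camera adjusted p = 1.5e-11, and adjusted p = 0.036 with an estimated correlation). Cth stood at 11.7 ± 5.17 against 0.597 ± 0.244 CPM (log2 fold change 4.29, SE 0.45, adjusted p = 1.2e-08), Chac1 rose 18.8-fold, Trib3 8.07-fold and Eif4ebp1 4.88-fold. Amino acid transporters rose in 9 of 11 members (9 over the list alone), with a median of 0.77 (camera adjusted p = 4.7e-07, and adjusted p = 0.14 with an estimated correlation). Slc6a9 rose 8.41-fold and Slc7a3 7.12-fold. Glycolysis genes rose in 10 of 20 members and fell in 1 (10 and 1 over the list alone), with a median of 0.34 (camera adjusted p = 3.8e-05, and adjusted p = 0.14 with an estimated correlation). The lactate exporter gene Slc16a3 rose from 9.04 ± 1.44 to 38.8 ± 11.1 CPM and Tpi1 2.27-fold. With the unstimulated share subtracted 14, 6 and 6 members of these 3 lists rose, with medians of 0.68, 0.42 and 0.18 (camera adjusted p = 2.9e-10, 0.0062 and 0.04, and adjusted p = 0.084, 0.76 and 0.87 with an estimated correlation). The other largest rises were Gpt2 (12.7-fold), the heat shock gene Hspa1a (8.12-fold), Vegfa (6.02-fold) and Pck2 (5.37-fold).

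Cholesterol synthesis genes fell with CompA in 8 of 23 WT members (9 over the list alone), with a median of -0.24 (camera adjusted p = 0.053), and with the share subtracted in 18 members, with a median of -0.55 (camera adjusted p = 8e-13, and adjusted p = 0.33 with an estimated correlation). Insig1 fell from 103 ± 13.7 to 53.8 ± 5.07 CPM. Ribosome biogenesis genes passed in 1 of 23 members, Pes1 (1.15-fold, 0 over the list alone), and the list had a median of -0.02 and a mean of -0.04 while camera leaned upward (adjusted p = 0.54). The Pes1 call was lost without WT stimulated replicate 2 or 3 or CompA replicate 3 or 4 (adjusted p = 0.178, 0.0661, 0.05 and 0.0747). With the share subtracted 19 members fell, with a median of -0.43 (camera adjusted p = 1.4e-11, and adjusted p = 0.084 with an estimated correlation). Myeloid markers fell in 16 of 20 members (1 up and 18 down over the list alone), with a median of -4.15 (camera adjusted p = 5.6e-19, and adjusted p = 0.0086 with an estimated correlation), and with the share subtracted the median was -0.2 while camera leaned upward (adjusted p = 0.62). Adamdec1 and Clec4a1 fell from 19.5 ± 14.8 and 10.3 ± 6.6 CPM to no count, at least 441-fold and 234-fold lower. Emr4, Treml4, Igf1, Slco2b1 and Tgfbi fell to under 0.1 CPM and Mrc1 fell 617-fold. Adamdec1, Clec4a1, Treml4 and Mrc1 kept their call with the share subtracted. In all 4047 genes changed, 1425 up and 2622 down. Subtraction of the share left 2973, 1573 up and 1400 down, of which 546 rises and 560 falls were shared and 306 were called in the opposite direction.

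**Figure D3:**
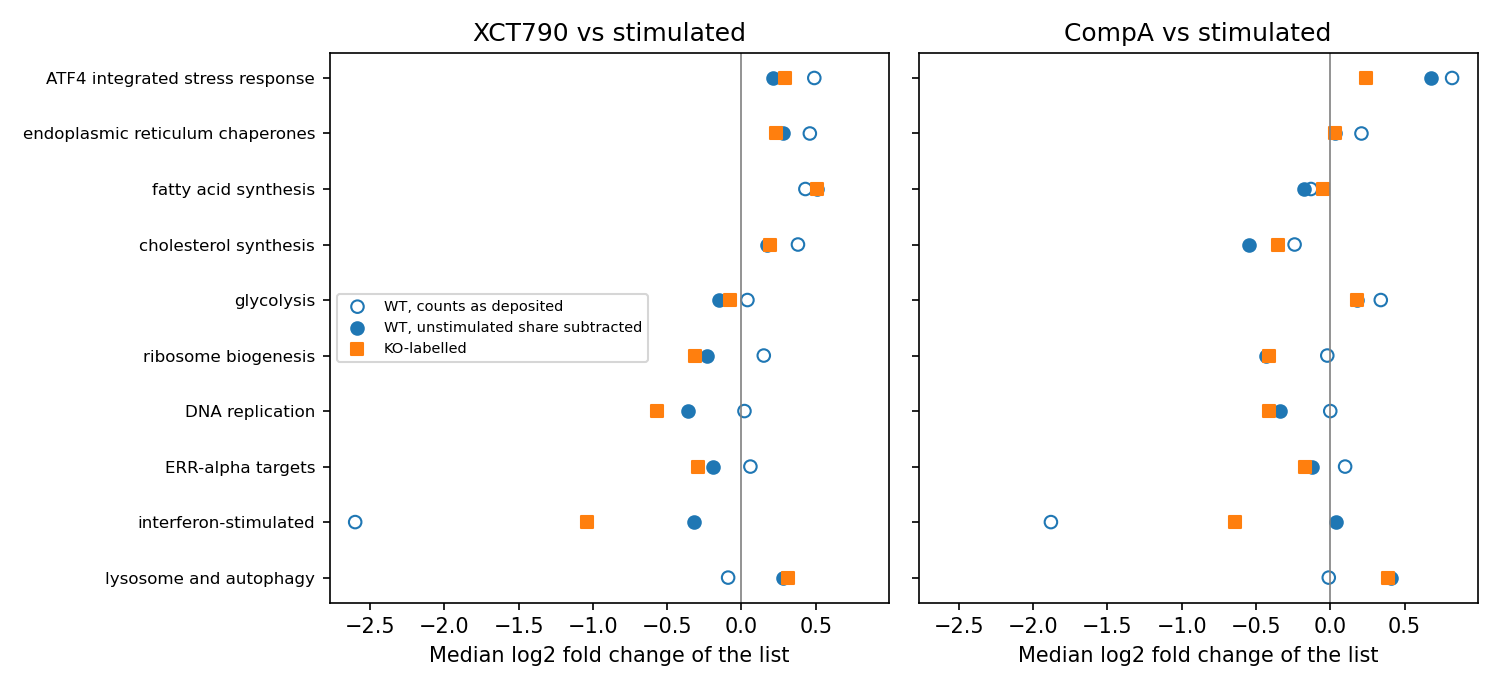
Median log2 fold change of 10 gene lists with XCT790 (left) and CompA (right) against stimulated cells, in WT with counts as deposited (open circles), in WT with the unstimulated share subtracted (filled circles) and in KO-labelled cells (squares). For interferon-stimulated genes with XCT790 the WT median was -2.6 as deposited and -0.32 with the share subtracted, and the KO-labelled median was -1.04.

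The inhibitors were set against each other at the same dose by weight, which need not be the same molar dose, in comparisons that do not use the WT stimulated libraries. Sterol and fatty acid synthesis genes were higher with XCT790 than with CompA in both genotypes, and glycolysis genes were lower. In WT, cholesterol synthesis genes were higher in 20 of 23 members (20 over the list alone), with a median of 0.7 (camera adjusted p = 1.5e-31, and adjusted p = 0.027 with an estimated correlation). In KO-labelled cells they were higher in 11 members (19 over the list alone), with a median of 0.5 (camera adjusted p = 2e-25, and adjusted p = 0.042 with an estimated correlation). Insig1 was 3.13-fold higher in WT and 2.54-fold in KO-labelled cells. Fatty acid synthesis genes were higher in 7 of 13 WT members (9 over the list alone) and 6 of 13 KO-labelled members (6 over the list alone), with medians of 0.6 and 0.43 (camera adjusted p = 2.7e-09 and 4.4e-08, and adjusted p = 0.027 and 0.042 with an estimated correlation). Scd2 stood at 128 ± 11.3 with XCT790 against 29.4 ± 7.09 CPM with CompA in WT and at 145 ± 47.7 against 41.5 ± 11.4 CPM in KO-labelled cells. Glycolysis genes were lower in 9 of 20 WT members (10 over the list alone) and 4 of 20 KO-labelled members (6 over the list alone), with medians of -0.32 and -0.27 (camera adjusted p = 5.2e-08 and 6e-06, and adjusted p = 0.069 and 0.14 with an estimated correlation). The 4 KO-labelled calls (Tpi1, Pfkfb3, Pkm and Pfkp) were lost in the fit of only these 2 groups (adjusted p = 0.124, 0.0724, 0.118 and 0.104) and each without 1 or more of XCT790 replicates 1, 2 and 3 and CompA replicates 2, 3 and 4 in turn (0.0509 to 0.14).

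ATF4 stress response genes were lower with XCT790 than with CompA in 6 of 22 WT members (1 higher and 13 lower over the list alone), with a median of -0.59 (camera adjusted p = 1e-06, and adjusted p = 0.11 with an estimated correlation). In KO-labelled cells none of the 22 passed with edgeR (also over the list alone), with a median of -0.02, a mean of 0.03 and camera upward (adjusted p = 0.65). Atf5 had a log2 difference of 0.59 (SE 0.2, adjusted p = 0.12) and Eif4ebp1 of -0.27 (SE 0.2, adjusted p = 0.61). Nr4a1 and Nr4a3 were lower with XCT790 in WT by 1.99-fold and 2.25-fold (adjusted p = 0.0051 and 3.3e-05) and in KO-labelled cells by 1.93-fold and 2.09-fold (adjusted p = 0.016 and 0.00037). The KO Nr4a1 call was lost without CompA replicate 1 (adjusted p = 0.0845) or XCT790 replicate 3 or 4 (0.0706 and 0.0544) and in the fit of only these 2 groups (0.0932). Esrra was lower with XCT790 by 1.34-fold in WT (adjusted p = 0.043) and 1.5-fold in KO-labelled cells (adjusted p = 0.012). The WT Esrra call was lost without 7 of the 8 libraries in turn, all but CompA replicate 2 (adjusted p from 0.0508 to 0.12), in limma-voom (0.0521) and with no filter (0.0585). The KO Esrra call was lost in the fit of only these 2 groups (0.101), as were those of Spin4 (0.0821) and Gsn (0.0709). Other large differences in WT were Rgs2 and Cpd (4.3-fold and 3.41-fold higher) and the heat shock genes Hspa1a and Hspa1b (43.5-fold and 13.7-fold lower), whose copies may share reads. In KO-labelled cells Spin4 and Maged2 were 3.3-fold and 2.67-fold higher with XCT790 and Gm14718 and Gsn 2.64-fold and 2.47-fold lower.

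The inhibitors differed in 1161 genes in WT, 534 higher and 627 lower with XCT790. This was 2046 with the replicate block, 2854 in the fit of only these 2 groups, and 751 and 749 without XCT790 replicate 1 or 3. In KO-labelled cells they differed in 400 genes, 243 higher and 157 lower, and the share of higher genes of 60.8 percent was 44.2 percent with library totals. The KO-labelled count was 995 with the replicate block, 619 with DESeq2 and 73 in the fit of only these 2 groups. It was 228 and 265 without XCT790 replicate 1 or 3 and 186 without CompA replicate 4.

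Whether the inhibitors moved the same genes was asked across the 12332 tested genes, which are not independent replicates. In WT the log2 fold changes of XCT790 and CompA correlated at 0.92, with 526 genes up and 1953 down in both where independent lists would share 120 and 530, and 35 in opposite directions. The comparisons share the WT stimulated libraries. Simulated unchanged groups gave a correlation of 0.5, and with the shared libraries divided the correlation was 0.86. The covariance was 1.52 against a simulated 0.0281. With the unstimulated share subtracted the correlation was 0.8, or 0.22 with the libraries divided, and the covariance was 0.5. In KO-labelled cells the correlation was 0.63, or 0.13 with the libraries divided, and the covariance was 0.14 against a simulated 0.0261. There 503 genes rose and 416 fell with both inhibitors, where independent lists would share 77.9 and 56.9, and 2 changed in opposite directions. The simulated correlation was 0.5, with 0.05 genes called in both on average.

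The difference between KO-labelled and WT stimulated cells was set against each inhibitor's effect, to ask whether genotype and inhibitors moved the same genes. In WT the correlations were 0.84 with XCT790 and 0.82 with CompA, where simulation gave 0.5 and divided libraries gave 0.77 and 0.75. The covariances were 1.23 and 1.22 against simulated values of 0.028 and 0.0274. For XCT790 235 genes were higher and 1692 lower in both comparisons, where independent lists would share 75.8 and 446, and for CompA 215 and 1590, where they would share 104 and 470, with 40 and 82 in opposite directions. Both comparisons are made against the WT stimulated libraries with their myeloid sum of 819 ± 287 CPM. Subtraction of the unstimulated share gave correlations of 0.62 and 0.6, or 0.13 and 0.15 with the libraries divided. Against the inhibitor effects in KO-labelled cells the correlations were -0.22 and -0.24, where simulation gave -0.5 for each, and -0.08 and -0.1 with the libraries divided. The covariances were -0.114 and -0.136 against simulated values of -0.0263 and -0.0262. There 25 genes were higher and 17 lower in both for XCT790 and 28 and 30 for CompA, where independent lists would share 56 and 112, and 91.8 and 201, and 480 and 810 changed in opposite directions. With the share subtracted these counts were 84 and 37 for XCT790 (51.7 and 15.5 by chance, 40 opposite) and 139 and 62 for CompA (83.1 and 26.5 by chance, 39 opposite). The correlations were then -0.08 and -0.06, and 0.11 for each with the libraries divided.

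Interaction terms tested whether the genotypes answered differently. For stimulation, oxidative phosphorylation genes rose further in KO-labelled cells, from a lower start, in 73 of 75 members (73 over the list alone), with a median interaction of 0.77 (camera adjusted p = 1.2e-19, and adjusted p = 0.52 with an estimated correlation). Cycs had an interaction log2 fold change of 0.92 (SE 0.18, adjusted p = 0.00045), Cox5a of 0.86 and Sdhd of 0.92. Cycs and Sdhd were not called with the share subtracted (adjusted p = 0.0537 and 0.0572). With the share subtracted 10 of the 75 passed, with a median of 0.51 (camera adjusted p = 1.4e-08, and adjusted p = 0.7 with an estimated correlation). Myeloid markers fell further in KO-labelled cells in 14 of 20 members (1 the other way and 15 over the list alone), with a median of -2.61 (camera adjusted p = 2.4e-12, and adjusted p = 0.083 with an estimated correlation), and with the share subtracted the median was 0.75 (upward, adjusted p = 0.022, and adjusted p = 0.38 with an estimated correlation). Ramp3 (2.01), Apol7c (1.69) and Dnajc15 (1.49) had the largest positive interactions and Col14a1, Emr4 and Cd163 the largest negative ones. Apol7c, Col14a1, Emr4 and Cd163 were not called with the share subtracted (adjusted p = 0.124, 1, 0.788 and 0.118). In all 4161 genes passed, 2126 positive and 2035 negative, 2669 without WT unstimulated replicate 1, 2394 in the fit of only these 4 groups and 1470 with the share subtracted. The share of positive interactions was 51.1 percent, and 22 percent with library totals, which moved the median of all genes by -0.24.

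For XCT790 the interactions were led by macrophage genes, which fell from the WT stimulated level but were already near zero in KO-labelled stimulated cells. Myeloid markers were positive in 15 of 20 members (17 over the list alone), with a median of 4.37 (camera adjusted p = 2.6e-21, and adjusted p = 0.0052 with an estimated correlation). C1qa had an interaction of 6.83. Itgad, Ptgs1 and Emr4 had the largest positive interactions, and Cks2 (-0.95), Fam195a (-0.84) and Trip13 (-0.84) the largest negative ones. The Trip13 call was lost without WT stimulated replicate 2 or 3, WT XCT790 replicate 3, KO-labelled stimulated replicate 3 or 4 or KO-labelled XCT790 replicate 2 or 3 (adjusted p from 0.053 to 0.111). The Emr4 call was lost without KO-labelled stimulated replicate 2 (0.0502) or XCT790 replicate 2 (0.163) or 3 (0.175). In all 3049 genes passed, 2158 positive and 891 negative, a positive share of 70.8 percent that was 56.7 percent with DESeq2 size factors. Just 1 gene passed with the unstimulated share subtracted, and the myeloid median was 0.35 while camera leaned downward (adjusted p = 0.96).

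For CompA the same myeloid genes were positive in 15 of 20 members (16 over the list alone), with a median of 4.61 (camera adjusted p = 8.3e-24, and adjusted p = 0.0029 with an estimated correlation), C1qa at 7.43, and with the share subtracted the median was 0.59 (adjusted p = 0.71). ATF4 stress response genes rose less in KO-labelled cells, in 10 of 22 members with 1 the other way (12 and 1 over the list alone), with a median of -0.62 (camera adjusted p = 6.3e-05, and adjusted p = 0.28 with an estimated correlation). Phgdh had an interaction of -0.85 (SE 0.16, adjusted p = 0.00038), Psat1 of -1.01 and Shmt2, an enzyme of serine use, of -0.6. Cth (-2.15), Slc6a9 (-1.45) and Asns, asparagine synthetase (-1.26), had the largest negative interactions and Slco2b1, Emr4 and Tgfbi the largest positive ones. The Cth call was lost in limma-voom (adjusted p = 0.0716) and without KO replicate 2 in every condition (0.0961). The Slco2b1 call was lost without KO-labelled CompA replicate 2 (adjusted p = 0.203), and the Emr4 call without WT CompA replicate 1 or 3, KO-labelled stimulated replicate 2 or 4 or KO-labelled CompA replicate 1 or 3 (0.0519 to 0.193). In all 2661 genes passed, 1922 positive and 739 negative, 4161 with the replicate block and 1772 without WT stimulated replicate 2. The positive share of 72.2 percent was 58.4 percent with DESeq2 size factors and 82.7 percent with library totals, which moved the median of all genes by 0.12. Only 3 genes passed with the unstimulated share subtracted, and the ATF4 median was -0.47 with no member called (camera adjusted p = 1.5e-10, and adjusted p = 0.099 with an estimated correlation).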

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

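The tests in this part were chosen after the results were seen. A library was singled out where its gap to the nearest other library of its group was, as a part of the group's range, above Dixon's 95 percent critical value, a rule that chance meets in about 1 in 20 groups. It was met in 7 of 48 checks of library measures and 13 of 144 checks of genes. Differences between genotypes were singled out by a called interaction term.

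The WT stimulated libraries held genes that the other stimulated groups had nearly lost, at 0.206, 0.35, 0.29 and 0.197 of the unstimulated level, by library totals. If unstimulated material of the same run had been mixed in, the myeloid, B cell and naive lists would give the same share within a library. Their largest ratio was 1.02 to 1.32 in replicates 1 to 3 but 1.52 in replicate 4, past the written limit of 1.5, and a bootstrap of list members added after that was seen gave 1.13 to 2.41. The 125 genes stood at nearly 1 ratio in each library, with quartile ratios of 1.08 to 1.12, and each library followed the unstimulated library of its own run (r of 0.86 to 0.97, at most 0.05 with other runs). Both met the limits written for mixing. As 1 limit was passed in replicate 4, by less than its spread, mixing may account for the pattern but stays open. A weaker response of WT T cells alone would not keep macrophage and B cell genes, whose lowest myeloid share was 0.197, and a library size or composition factor would cancel in the ratio of these genes over that of all genes of a library, which was 0.218 to 0.405 in WT stimulated and 0.00307 to 0.022 in the other stimulated libraries, the lowest 9.92 times the highest other. Why unstimulated transcripts remained was not tested further.

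In all 4 conditions 141 genes were higher and 23 lower in KO-labelled cells, and Nr4a1 was not among the lower genes. Carried-over DNA of another strain around Nr4a1 would put such genes near it on chromosome 15. Within 10 Mb 3 of 113 genes were called (Acvrl1, Csrnp2 and Prr13), 2.65 percent against 1.34 percent of the genome, a ratio of 1.99 that 13.1 percent of other windows reached, so this could not be told from chance. The biological explanation, loss of Nur77 itself, could not be separated from it with these libraries.

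KO replicate 2 stood apart with B cell marker sums of 1320 CPM when stimulated and 1350 CPM with CompA. Other lymphocytes carried through the isolation in that run would raise B cell and CD8 genes in all 4 conditions. Of 14 B cell list members 13 were highest in replicate 2 in all 4 KO conditions, as were Cd8a and Cd8b1 and 5.03 percent of all genes. These members make up the sum that showed the pattern, and libraries of a run deviate together, so the count does not support the explanation and leaves it open. Igj stood far above the other libraries there, at 103 CPM with XCT790 and 81.4 CPM with CompA, and no biological explanation was tested.

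Other libraries far from the rest of their group were these. WT stimulated replicate 3 had 20.8 megacounts. Rn45s made up 0.609 percent of counts in WT CompA replicate 3 and 1.97 percent in KO unstimulated replicate 3. The myeloid sum was 195 CPM in WT XCT790 replicate 2 and the CD8 and NK sum 57.3 CPM in WT CompA replicate 4. Esrra stood at 42.9 CPM in KO stimulated replicate 1, and Trib3 and Gsn at 20 and 28.5 CPM in KO XCT790 replicate 2. In WT CompA replicate 2 Chac1, Gpt2, Trib3 and Vegfa stood at 5.8, 15.9, 21.2 and 7.88 CPM. In WT stimulated replicate 2 Hfe, Scd2, Treml4 and Igf1 stood at 25.5, 71, 34.9 and 25.7 CPM.

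The genotypes differed in their change with stimulation in 4161 genes, with XCT790 in 3049 and with CompA in 2661. For stimulation the interaction log2 fold changes were 2.01 for Ramp3, 1.69 for Apol7c, 1.49 for Dnajc15, -9.26 for Col14a1, -8.02 for Emr4, -7.88 for Cd163, -2.02 for Nr4a2 and -1 for Nr4a3. For XCT790 they were 10.15 for Emr4, 8.89 for Ptgs1 and for Itgad, -0.95 for Cks2, and -0.84 for Fam195a and for Trip13. For CompA they were 10.59 for Slco2b1, 10.18 for Emr4, 9.72 for Tgfbi, -2.15 for Cth, -1.45 for Slc6a9 and -1.26 for Asns. The large positive values rest on WT stimulated levels and on counts near 0 elsewhere.

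Other divisions of the libraries compared were fitted to ask whether chance can be excluded. For KO against WT and for each inhibitor in WT the real division alone, 1 of 35, gave as many called genes. The real and highest other counts were 2294 and 1 for KO against WT unstimulated, 1438 and 0 stimulated, 1333 and 29 with XCT790 and 716 and 97 with CompA, and 3202 and 393 for XCT790 and 3951 and 0 for CompA in WT. For the interactions whole runs of library numbers were exchanged between the genotypes, and the real division alone of 35 gave as many, with 2394 and 1 for stimulation, 2493 and 0 for XCT790 and 2056 and 0 for CompA. Libraries exchanged regardless of run gave at most 643. In the other 6 comparisons libraries of a run deviate together, and the 8 divisions that part every run are too few for a share under 0.05. The real and highest other counts were 8130 and 0 for stimulation in WT and 9342 and 0 in KO, 240 and 0 for XCT790 and 860 and 0 for CompA in KO, and 2854 and 0 for XCT790 against CompA in WT and 73 and 0 in KO. Divisions that kept libraries of a run together gave at most 26 genes.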

How the results depend on the processing

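Other size factors, filters and the DESeq2 and limma-voom tests kept nearly all calls and every direction, and the cause of each change below was not tested unless stated. DESeq2 moved 1 count past 1.5 times, XCT790 against CompA in KO (619). The replicate block gave 2642 genes for XCT790 and 3635 for CompA in KO, 4161 for the CompA interaction, and 2046 and 995 for XCT790 against CompA in WT and KO. It kept 391 calls of named genes, lost 4 and added 6, and it kept all 63 list calls. Fits of only the groups compared, with fewer samples, gave 2294 and 1438 for KO against WT unstimulated and stimulated, 2394 for the stimulation interaction, 240 and 860 for XCT790 and CompA in KO, and 2854 and 73 for XCT790 against CompA in WT and KO, and lost 48 gene calls. With the correlation estimated per list 49 of 63 list calls were lost.

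Leaving out 1 library gave ranges of 2060 to 5317 for KO against WT unstimulated, 2669 to 5098 for the stimulation interaction, 771 to 1634 for XCT790 in KO, 1772 to 3361 for the CompA interaction, 749 to 1207 and 186 to 384 for XCT790 against CompA in WT and KO, and 660 to 1277 and 549 to 1066 for KO against WT with XCT790 and CompA. Across these fits 100 gene calls were lost, 13 added and 3372 kept. Omitting KO replicate 2, chosen after seeing the data, lost 12 gene calls, added 1 and kept 251, and lost no list call.

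Subtracting the unstimulated share, also chosen after seeing the data, gave 1116 genes for KO against WT stimulated, 1074 for XCT790 in WT, and 1470, 1 and 3 for the stimulation, XCT790 and CompA interactions. It turned the sign, for KO against WT stimulated, of C1qb (1.92), Pik3ip1 (1.78), Il7r (0.3), Klf2 (0.42), S1pr1 (2.37), Itgae (0.62), Ddx58 (2.01), Oas2 (1.5), Idh3a (-0.02) and Cycs (-0.07) and of the myeloid (0.25), naive (0.09), interferon (1.47), ERR-alpha (-0.08) and oxidative phosphorylation (-0.03) lists. It did so for Col14a1 (0.97), C1qa (0.62), C1qb (3.11) and the myeloid list (0.75) in the stimulation interaction, for Ptgs1 (2.88), Siglece (0.46), Acss2 (1.13), C1qb (1.19), Ddx58 (0.6), Rtp4 (0.02) and the ERR-alpha list (-0.19) with XCT790 in WT, for C1qb (1.7) and Pes1 (-0.16) with CompA in WT, for Ptgs1 (-2.68) and C1qb (-1.03) in the XCT790 interaction and for C1qb (-1.14) in the CompA interaction. The cause was the removal of counts by construction. Correlations between comparisons with it were 0.8 for the inhibitors in WT, 0.62 and 0.6 for genotype with XCT790 and CompA in WT, and -0.08 and -0.06 in KO. As deposited, with the shared libraries divided, they were 0.13 for the inhibitors in KO, and -0.08 and -0.1 for genotype with XCT790 and CompA in KO.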

Other observations

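Some genes differed between the genotypes in every condition, and those named were chosen after their values were seen. Il10 (chromosome 1, 131019845 to 131024970) was higher in KO-labelled cells in all 4 conditions. Its log2 differences were 2.57 unstimulated, 3.01 stimulated, 2.94 with XCT790 and 2.79 with CompA. Spp1, which encodes osteopontin, was higher by 3.16, 3.1, 3.58 and 3.52 in the same order, and Areg, the growth factor amphiregulin, by 2.54, 2.4, 2.17 and 1.82. Wdfy1, an adaptor of endosomal Toll-like receptors (chromosome 1, 79702262 to 79776143), was lower by 2.3, 3.83, 3.68 and 3.79, and stood at 24.5 ± 0.954 CPM in WT and 4.97 ± 0.487 CPM in KO-labelled unstimulated cells (SD, n = 4). Nnt, the mitochondrial transhydrogenase, was lower by 0.98, 0.61, 0.57 and 0.66. Strain differences outside the Nr4a1 region were not tested.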
